A study of Homo sapiens with 8 samples.

How the data were processed

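RNA was measured by sequencing in 8 libraries of LNCaP cells, in 4 groups of 2 (control hairpin, METTL3 knockdown, wild-type rescue and mutant rescue). Per the labels, total RNA was extracted with TRIzol from cells infected with lentivirus and selected with puromycin at 1 µg/ml, and libraries were made with a stranded messenger RNA kit. The authors' notes name CASAVA, STAR 2.5.2b, featureCounts, DESeq2 and the genome build hg19, without their parameters. The deposited table holds raw counts per gene for each library, and a column of other kind, the gene length in bases. No coordinates are given because the annotation at hand is of another build; it was used only for exon structure.

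Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr by group (minimum count 10, minimum total 15), which left 15289 of 27140, and libraries were scaled by TMM. A quasi-likelihood model with 1 mean per group was fitted to all 8 libraries with robust dispersion, so that the groups share an estimate of the spread. The 6 pairwise comparisons were tested two-sided, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05 without a minimum fold. Standard errors are the absolute log2 fold change divided by the square root of F. At 2 libraries against 2 no exact permutation test can reach 0.05, and all adjusted p-values come from models fitted across genes. Totals of 15200343 to 17893241 counts set the depth, and counts without molecular identifiers are not independent molecules.

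Of 38 gene lists, 35 had at least 5 tested members. They were tested with camera in limma 3.58.1 on voom values with a preset correlation of 0.01, adjusted over the lists of a comparison, and again with a correlation estimated per list and with fry. The lists, the comparisons, the tests and the alternatives below were chosen before the data were examined, except those said to be chosen after seeing the data or the results. Named genes include METTL3 and KLK3 and, per comparison, come from the 10 largest rises and the 10 largest falls among called genes with a mean of at least 5 CPM, a gene symbol that is not a clone name and no overlap between the 2 groups' libraries. For lists, the members named are among those with the largest changes. Some genes that meet these rules are not named. Overlaps of calls were compared with the number expected if calls were independent, and correlations with 100 simulations without effects that share the same libraries.

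Alternatives were DESeq2 1.42.0 size factors, no filter on low counts, the DESeq2 Wald test, only the groups compared, a minimum absolute log2 fold change of 1, genes with a mean of at least 10 CPM, the replicate number as a block, each library left out in turn (the other library of its group assumed to vary like the other groups), an estimated correlation and fry. An alternative that removes the length trend was chosen after seeing the data: a lowess curve (span 0.3) of each library's log2 CPM against the mean library over log2 gene length served as an offset. Overlaps of comparisons that share a group were also counted with 1 library of that group for each comparison, again chosen after seeing the data. The steps were tested on simulated data of the same design. Lists with fewer than 5 tested members were not tested and, like genes on the Y chromosome, were left out of the text.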

Results

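LNCaP is a human prostate adenocarcinoma line, and METTL3 is the catalytic subunit of the complex that methylates adenosines in messenger RNA. Transcripts were counted per gene by RNA sequencing in 8 LNCaP libraries of 4 stable lines, with 2 libraries each. The lines carried a control hairpin with a vector, a hairpin against METTL3 with a vector (knockdown), or that hairpin with a resistant METTL3. The resistant METTL3 was wild-type (wild-type rescue) or lacked catalytic activity (mutant rescue). For the control and the knockdown the titles say only vector, not what it holds. The libraries held 15200343 to 17893241 counts, and 15289 of the 27140 genes had enough counts to be tested. The 2 libraries of a line differed by more than sampling noise, with chi-square per degree of freedom of 1.26 in the control, 1.21 in the knockdown, 1.36 in the wild-type rescue and 1.21 in the mutant rescue. The ratio of the median gene to its expected value, which single genes hardly move, was 1.12, 1.16, 1.25 and 1.21 in that order. The labels do not say whether the 2 libraries of a line come from separate cultures. Each test therefore measures only the spread between these libraries, which was small (biological coefficient of variation 1.40%).

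METTL3 stood at 68.4 ± 0.0784 CPM (counts scaled to a common library size) in the control (SD, n = 2) and at 28.8 ± 3.64 in the knockdown, a log2 fold change of -1.26 (SE 0.05, edgeR adjusted p = 1.50e-48). It rose to 317 ± 10.8 in the wild-type rescue and 333.7 ± 0.632 in the mutant rescue, log2 fold changes over the control of 2.21 (SE 0.03) and 2.29 (SE 0.03). Counts of the hairpin target and of the introduced copies cannot be separated, because both fall on the same gene. METTL3 differed between the rescues by a log2 fold change of 0.07 (SE 0.03, edgeR adjusted p = 0.0161), and for METTL3, mutant rescue vs wild-type rescue, the call ended with DESeq2 (adjusted p = 0.193) or without mutant rescue replicate 1 (0.0687), mutant rescue replicate 2 (0.0926) or wild-type rescue replicate 1 (0.346).

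**Figure D1:**
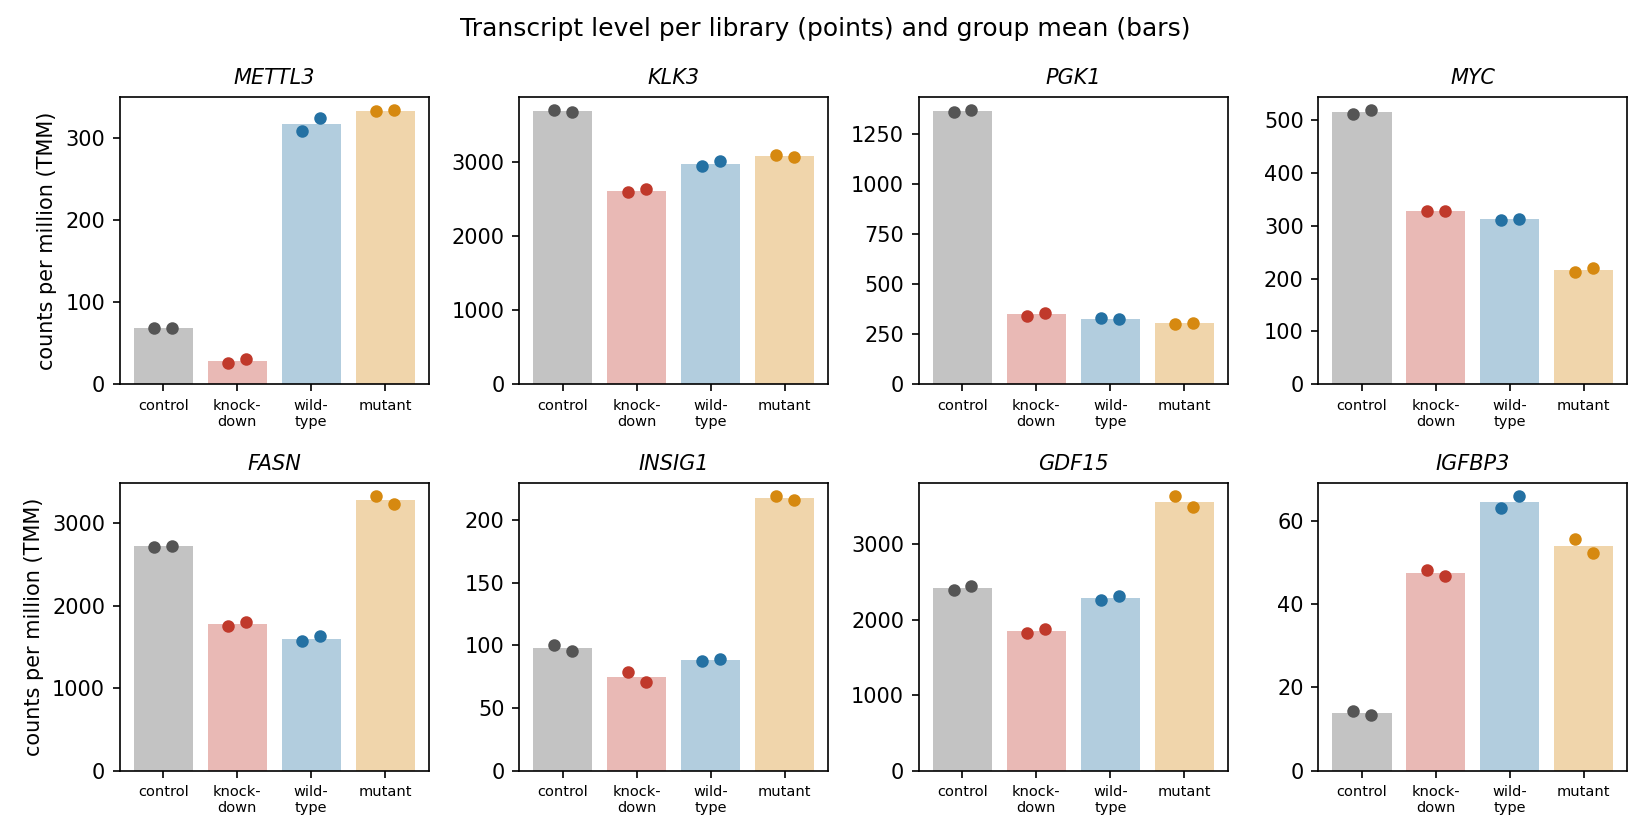
Expression in CPM (TMM-scaled, y axes from 0) of 8 genes in the 8 libraries, by line, with points for libraries and bars for the mean of 2. METTL3 was 28.8 in the knockdown and 317 in the wild-type rescue, while PGK1 stood at 1365 in the control and between 305 and 350.4 on average in the other lines.

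The first comparison asks which transcripts change when METTL3 is depleted. Among genes that met the naming rules (called, a mean of at least 5 CPM, no clone name and no overlap), the largest rise on knockdown was in SI, an intestinal disaccharidase. It went from 1.55 ± 0.494 to 18.2 ± 0.264 CPM (SD, n = 2, log2 fold change 3.55, SE 0.16). SLITRK6 rose by 3.08 on the log2 scale (SE 0.16), the chemokine CCL20 by 2.56 (SE 0.08), and UGT2B15, an enzyme that conjugates androgens, by 2.38 (SE 0.06). PGK1, a glycolytic enzyme, fell most among genes that met these rules, from 1365 ± 5.77 to 350.4 ± 10.9 CPM (log2 fold change -1.96, SE 0.02, edgeR adjusted p = 1.97e-136). PGK1 was no higher in either rescue (327.5 and 305 CPM), and the labels do not say whether the constructs carry sequence of this gene or of its promoter. CHAC1, which degrades glutathione, had a log2 fold change of -1.60 (SE 0.13), TNS4 of -1.48 (SE 0.11), S100P of -1.43 (SE 0.10) and the prostate noncoding RNA PCAT1 of -1.41 (SE 0.07). KLK3, which encodes prostate-specific antigen, fell by 0.50 on the log2 scale (SE 0.02). By edgeR, 3506 genes rose and 3831 fell, with a median absolute log2 fold change of 0.294 among those called. Of these, 514 reached a log2 fold change of 1 in either direction, and DESeq2 called 4767. In 11086 of the 15289 genes both libraries of one line lay above both of the other, which chance gives in 33.3% of genes.

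Several fixed gene groups moved as sets on knockdown. Of 34 ATF4 targets and amino acid synthesis genes, 29 fell, 2 rose and 3 were not called (30 and 2 adjusted over the list alone), with ATF4 at a log2 fold change of -0.78 (SE 0.03) and STC2 at -0.97 (SE 0.05), while VLDLR was at 0.72 (SE 0.08). Among 36 MYC and ribosome biogenesis targets 30 fell and 2 rose, the same counts adjusted over the list alone, and MYC itself fell by 0.65 (SE 0.02). Luminal epithelial markers fell in 15 of 19, with 1 rise (15 and 1 adjusted over the list alone), among them AGR2 (-0.84, SE 0.08), CLDN3 (-0.64, SE 0.03) and KRT18 (-0.46, SE 0.03). Of 18 fatty acid synthesis genes 10 fell and 1 rose (10 and 1 adjusted over the list alone), including FASN at -0.62 (SE 0.02) and ELOVL5 at -0.52 (SE 0.02). Interferon-stimulated genes rose in 23 of 39, with 3 falls (23 and 4 adjusted over the list alone), led by CXCL10 (1.59, SE 0.18), IFIT1 (1.33, SE 0.09) and IFI44 (1.20, SE 0.10). Histone genes, whose messages mostly lack a poly(A) tail, rose in 11 of 15 with no fall (12 adjusted over the list alone), including HIST1H2BC at 1.38 (SE 0.11). The share of counts in the ribosomal RNA genes listed as RNR1 and RNR2 also separated these lines, at 3.22% and 3.27% in the control libraries and 2.44% and 2.49% in the knockdown (2.71% to 2.79% in the rescues). These 6 lists passed camera (adjusted p = 2.96e-18, 9.49e-12, 1.02e-06, 1.24e-06, 1.03e-05 and 1.24e-06 in that order). They are also the lists called with an estimated correlation, where adjusted p = 0.0205, 0.0456, 0.0454, 0.0454, 0.0456 and 0.0454.

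Androgen-induced genes fell in 23 of 40 and rose in 7 on knockdown, the same counts adjusted over the list alone (camera adjusted p = 2.99e-09; adjusted p = 0.0580 with an estimated correlation, or 0.0487 with the length trend also removed). KLK2, a kallikrein protease, fell by 0.94 (SE 0.02), the channel TRPM8 by 0.79 (SE 0.08) and the transporter ABCC4 by 0.76 (SE 0.02), whereas ACPP, prostatic acid phosphatase, rose by 1.39 (SE 0.07). Mitotic genes fell in 21 of 32 with 1 rise (22 and 1 adjusted over the list alone; camera adjusted p = 7.21e-04; adjusted p = 0.191 with an estimated correlation), and DNA replication genes fell in 16 of 35 with no rise (16 adjusted over the list alone; camera adjusted p = 0.00574; adjusted p = 0.0802 with an estimated correlation). Respiratory chain subunits rose in 27 of 46 and fell in 6, in both forms of the count (camera adjusted p = 1.11e-05; adjusted p = 0.0753 with an estimated correlation). On knockdown 17 of 35 lists were called. The fry test, which does not compare a list with other genes, called 27 lists, these 17 among them. Longer genes rose more in this comparison, with a Spearman rho over 11572 genes of 0.149.

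The wild-type rescue against the knockdown asks what changes when METTL3 is put back. METTL3 itself rose by 3.47 on the log2 scale (SE 0.04). Among genes that met the naming rules, which leave out those under 5 CPM, the next rises were CMC4 (0.69, SE 0.16), PBX4 (0.68, SE 0.16) and PPP1R32 (0.65, SE 0.16). The largest falls within the same rules were in POMK, a kinase of dystroglycan glycosylation (-1.14, SE 0.12), SFT2D2 (-1.07, SE 0.16), IGSF9B, which fell by 1.00 (SE 0.13), and the tyrosine kinase FRK (-0.92, SE 0.13). KLK3 rose by 0.19 (SE 0.02), while of 40 androgen-induced genes 19 fell and 4 rose, in both forms of the count (camera adjusted p = 2.94e-04; adjusted p = 0.173 with an estimated correlation). By edgeR 1652 genes rose and 2021 fell, with a median absolute log2 fold change of 0.189, and 35 genes passed a log2 fold change of 1. DESeq2 called 1705 genes, and its default filter gave CMC4, PBX4, PPP1R32, POMK, SFT2D2, IGSF9B and FRK no adjusted p. PBX4 was not called without knockdown replicate 2 (edgeR adjusted p = 0.0596) or wild-type rescue replicate 2 (0.115), and PPP1R32 was not called without knockdown replicate 1 (0.0721). Among genes picked after their values were seen, BASP1 had in the wild-type rescue 163 counts in replicate 1 and 39 in replicate 2, S100A6 77 and 10, and GSTP1 38 and 5, and without replicate 1 edgeR called 2979 genes.

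Ribosomal protein genes rose in 57 of 77 with no fall on adding wild-type METTL3 (59 adjusted over the list alone), with RPL39 at 0.25 (SE 0.06) and RPL37A at 0.20 (SE 0.02) on the log2 scale (camera adjusted p = 2.40e-35; adjusted p = 0.104 with an estimated correlation). Respiratory chain subunits rose in 25 of 46 and fell in 4 (27 and 6 adjusted over the list alone), including COX6A1 at 0.25 (SE 0.04; camera adjusted p = 1.27e-05; adjusted p = 0.104 with an estimated correlation). Fold change in this comparison fell with gene length, with a rho of -0.468 over 11572 genes. With the length trend removed, an alternative chosen after seeing the data, ribosomal protein genes rose in 16 and fell in 9 (camera adjusted p = 0.152). Respiratory chain subunits then rose in 3 and fell in 10 (median 0.01, camera direction down, adjusted p = 0.272). Ribosomal protein genes had also risen on knockdown, in 41 with 6 falls under that alternative (camera adjusted p = 1.37e-04, or 0.211 with an estimated correlation). Their rise with wild-type METTL3 was thus not a return toward the control. Integrin and adhesion genes fell in 11 of 26 and rose in 1 (14 and 1 adjusted over the list alone), among them TLN1 at -0.27 (SE 0.03) and ITGB1 at -0.26 (SE 0.03). That list had a camera adjusted p = 2.51e-05, or 0.0135 with the length trend removed, and adjusted p = 0.104 with an estimated correlation. MYC targets fell in 17 of 36 and rose in 1, in both forms of the count, with UTP20 at -0.43 (SE 0.06; camera adjusted p = 2.94e-04, or 8.19e-09 with the length trend removed; adjusted p = 0.173 with an estimated correlation). None of the 12 lists called here was called with an estimated correlation, where the smallest adjusted p was 0.104. The fry test called 19 lists, these 12 among them. With the length trend removed edgeR called 2623 genes, of which 2073 were among the 3673.

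**Figure D2:**
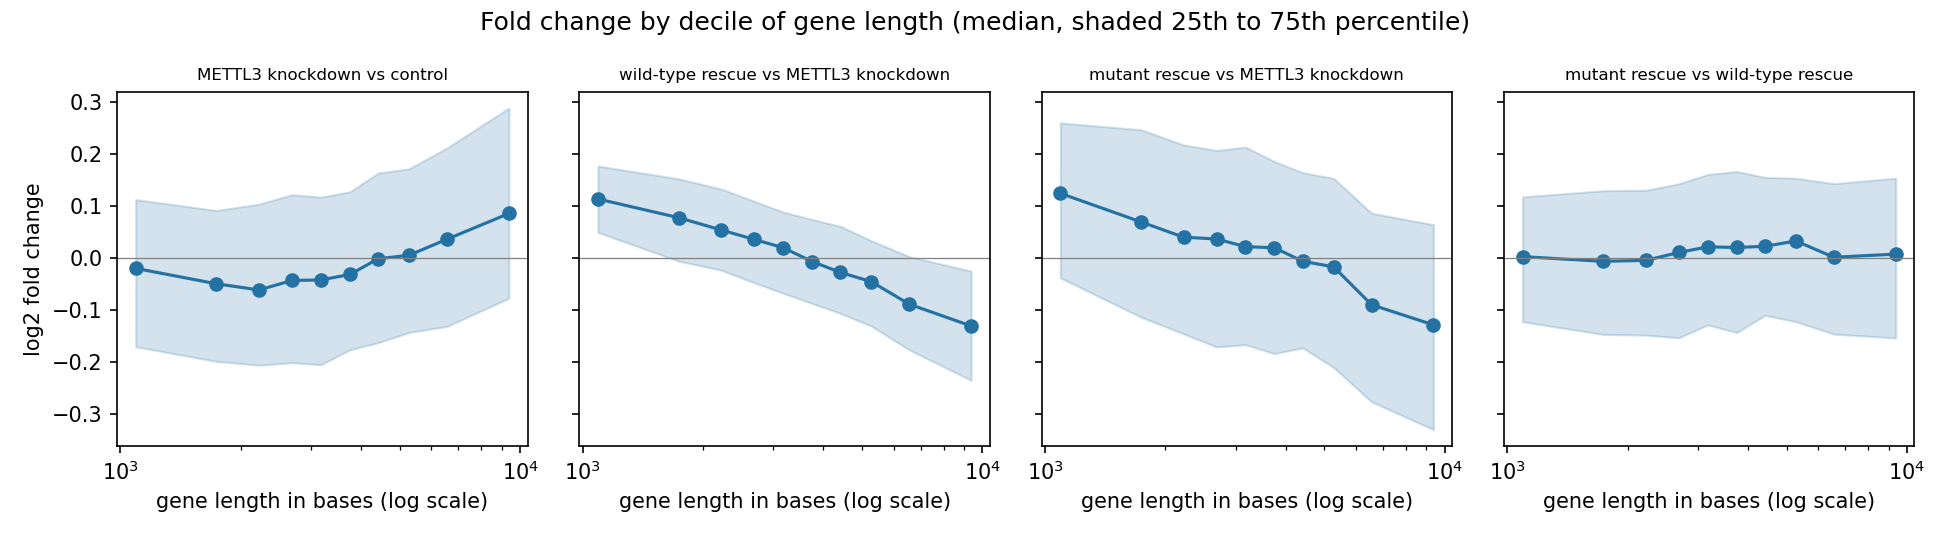
Median log2 fold change (points; shading, interquartile range) in 10 bins of gene length (x axis, bases, log scale) for 4 comparisons of the 8 libraries. On adding wild-type METTL3 the median went from 0.11 in the shortest bin to -0.13 in the longest, while mutant rescue against wild-type rescue had a rho of 0.0156.

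The mutant rescue against the knockdown asks what METTL3 without catalytic activity changes. After METTL3 (3.54, SE 0.04), the largest rises on the log2 scale among genes that met the naming rules were in LAMB2P1, a pseudogene of a laminin gene (1.97, SE 0.16), the stress gene GADD45B (1.75, SE 0.06) and the dopamine receptor DRD4 (1.75, SE 0.15). Falls among these genes were largest in the metalloproteinase MMP16 (-1.84, SE 0.11), SLITRK6 (-1.78, SE 0.13) and OR51E1, an olfactory receptor expressed in prostate (-1.73, SE 0.18). KLK3 rose by 0.24 (SE 0.02), while of 40 androgen-induced genes 18 fell and 9 rose (18 and 10 adjusted over the list alone; camera adjusted p = 0.0324; adjusted p = 0.248 with an estimated correlation). That list was not called with the length trend removed (0.0671), without mutant rescue replicate 2 (0.0510) or without knockdown replicate 2 (0.0587). By edgeR 3964 genes rose and 3945 fell, 380 of them by a log2 fold change of 1 or more. MYC targets fell in 32 of 36 and rose in 1, in both forms of the count (camera adjusted p = 7.31e-19; adjusted p = 0.0567 with an estimated correlation). Of 29 p53 targets 21 rose and 3 fell, in both forms of the count, with BBC3, which promotes apoptosis, at 1.46 (SE 0.05; camera adjusted p = 1.42e-09; adjusted p = 0.0578 with an estimated correlation). Ribosomal protein genes rose in 62 of 77 and fell in 1, in both forms of the count (camera adjusted p = 7.82e-20; adjusted p = 0.108 with an estimated correlation). Fold changes fell with gene length here too (rho -0.226), and with the length trend removed ribosomal protein genes rose in 35 and fell in 8 (camera adjusted p = 0.00145). Of the 19 lists called by camera, 0 was called with an estimated correlation; with the length trend removed, MYC targets, p53 targets, cholesterol synthesis genes and nuclear-retained RNAs were (adjusted p = 0.0431 each). Heat shock genes rose in 7 of 17 and fell in 7 (8 and 7 adjusted over the list alone), with a median of 0.10 but a downward camera call (adjusted p = 0.0324, or 0.134 with an estimated correlation). That call ended without a filter on low counts (camera adjusted p = 0.104) and with either control library left out.

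By their labels the rescue lines differ in whether the introduced METTL3 is active, so their comparison asks what depends on catalytic activity. INSIG1, a regulator of cholesterol synthesis, rose most among genes that met the naming rules. It went from 88.4 ± 1.09 CPM in the wild-type rescue to 217.6 ± 2.13 in the mutant rescue (SD, n = 2, log2 fold change 1.30, SE 0.04, edgeR adjusted p = 2.15e-74). The antisense RNA SLC7A11-AS1 was higher by 1.25 (SE 0.17), GADD45B by 1.18 (SE 0.05), and LAMB2P1 by 1.16 (SE 0.14). PTGS2, the inducible cyclooxygenase, fell by 1.38 (SE 0.13), FJX1 by 1.35 (SE 0.15), MMP16 by 1.28 (SE 0.12) and CFAP44 by 1.26 (SE 0.14). KLK3 differed by 0.05 (SE 0.02; edgeR adjusted p = 0.0154), a call that ended without mutant rescue replicate 1 (0.145) or wild-type rescue replicate 1 (0.192). By edgeR 3206 genes rose and 3101 fell, 185 of them by a log2 fold change of 1 or more, and DESeq2 called 3749 genes.

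MYC and ribosome biogenesis targets fell in 34 of 36 in the mutant rescue against the wild-type rescue and rose in 0, the same counts adjusted over the list alone, with MYC at -0.52 (SE 0.03), BOP1 at -0.78 (SE 0.10) and the nucleolar protein NCL at -0.67 (SE 0.02). Cholesterol synthesis genes rose in 14 of 24 and fell in 2 (15 and 2 adjusted over the list alone), with INSIG1 at 1.30 (SE 0.04) and MSMO1 at 0.81 (SE 0.04). Fatty acid synthesis genes rose in 10 of 18 and fell in 1 (11 and 1 adjusted over the list alone), with FASN at 1.04 (SE 0.02) and ACSS2 at 0.58 (SE 0.05). Of 29 p53 targets 20 rose and 1 fell, in both forms of the count, among them BBC3 (0.96, SE 0.05), CDKN1A, an inhibitor of the cell cycle (0.85, SE 0.02), and GDF15 (0.64, SE 0.02). ATF4 targets rose in 19 of 34 and fell in 6 (21 and 6 adjusted over the list alone), with CHAC1 at 1.11 (SE 0.12), and oxidative stress targets of NRF2 rose in 12 of 20 and fell in 2, in both forms of the count, with HMOX1 at 0.97 (SE 0.05). These 6 lists had camera adjusted p = 5.06e-22, 2.40e-11, 3.57e-08, 1.88e-12, 8.30e-06 and 3.00e-07 in the order given. With an estimated correlation their adjusted p = 0.0351, 0.0351, 0.0351, 0.0351, 0.0432 and 0.0432, the only calls of the 20 to hold there; with the length trend removed that of the NRF2 targets did not hold (0.0503). Mitotic genes fell in 16 of 32 with no rise (19 adjusted over the list alone; camera adjusted p = 1.50e-05; adjusted p = 0.0896 with an estimated correlation), including HMMR at -0.56 (SE 0.05). Androgen-repressed genes fell in 5 of 8 with no rise (5 and 1 adjusted over the list alone; camera adjusted p = 3.84e-05; adjusted p = 0.0504 with an estimated correlation), among them UGT2B15 at -1.10 (SE 0.05) and UGT2B17 at -0.60 (SE 0.05).

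**Figure D3:**
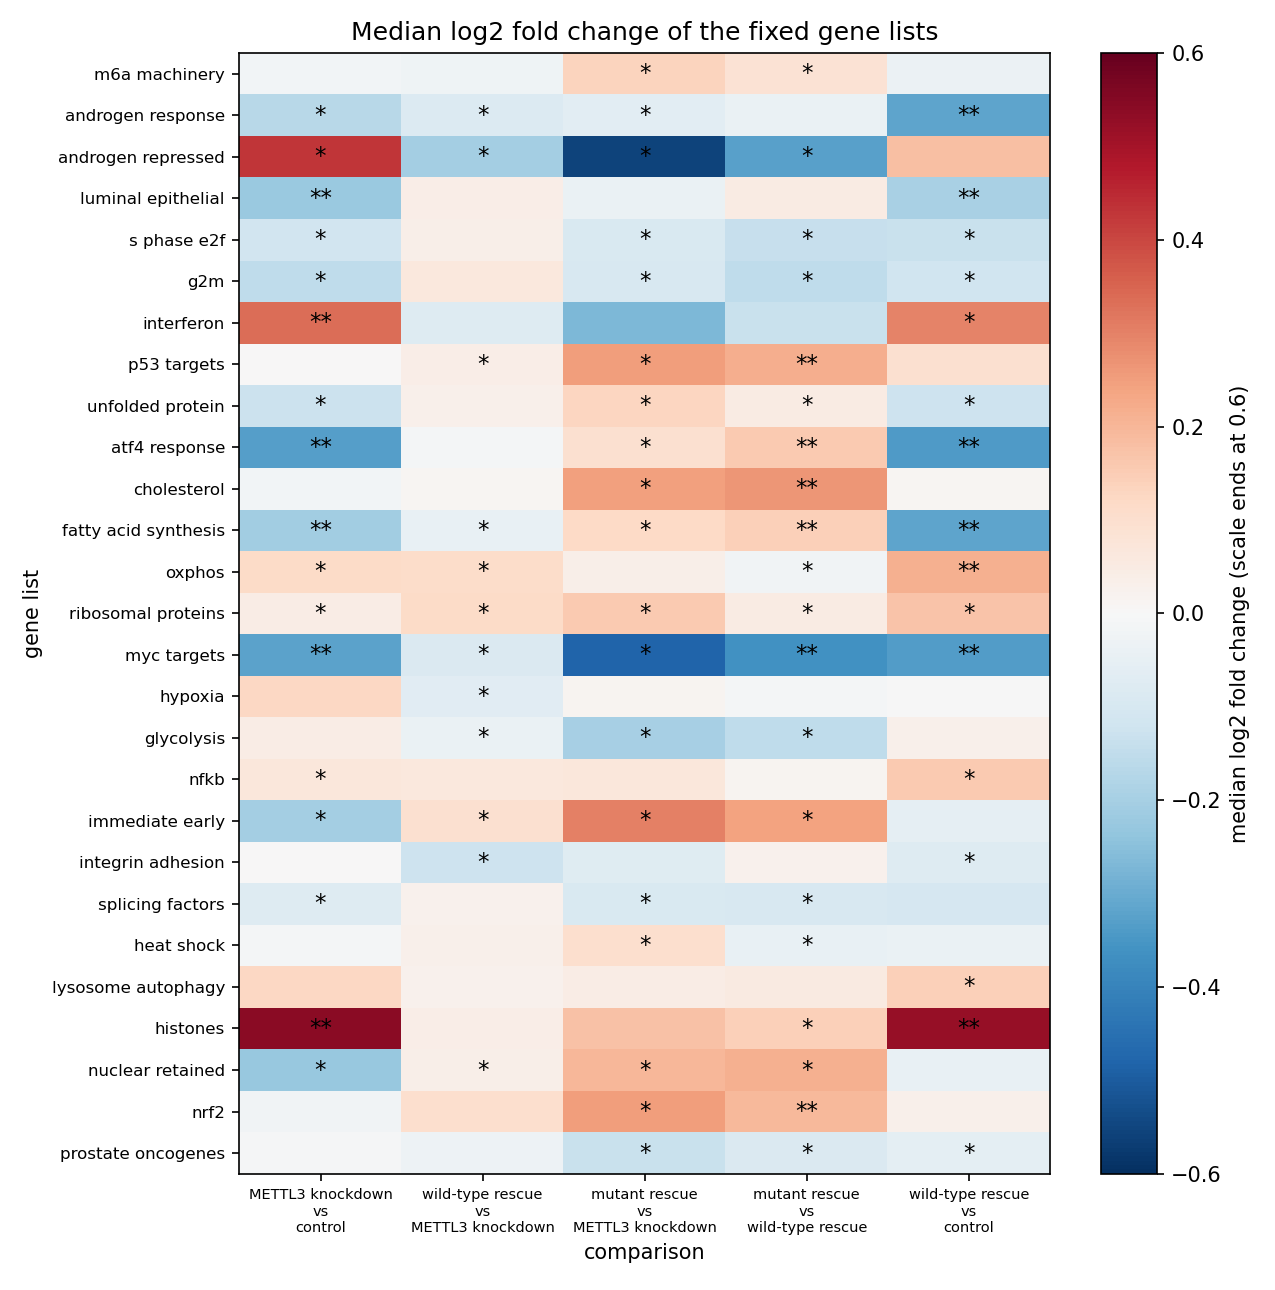
Median log2 fold change (colour, scale ends at 0.6) of the fixed gene lists called in at least 1 of 5 comparisons, with 1 column per comparison; * marks camera adjusted p under 0.05 and ** the same also with an estimated correlation. MYC targets had a median of -0.32 on knockdown and -0.36 in the mutant against the wild-type rescue, and histone genes one of 0.54 on knockdown. MYC targets were also called downward on adding wild-type METTL3 to the knockdown.

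The knockdown comparison and the rescue comparison share no library, so genes called in the same direction in both do not owe this to a common sample. HMOX1, which degrades heme, rose by 1.00 on knockdown and 0.97 in the mutant against the wild-type rescue, and the circadian repressor CRY2 by 0.58 and 0.70. SAMD13 had log2 fold changes of -0.74 and -0.83, AGR2 of -0.84 and -0.71, and ADAM7 of -0.70 and -0.82. Among the 7337 genes called on knockdown, 1688 were called in the same direction and 2009 in the opposite direction between the rescues, against 1512 and 1514 if the calls were independent. Over all tested genes the changes correlated with Pearson r = -0.127 and Spearman rho = -0.0612, and 47.2% of the knockdown calls had the same sign. Correlations are across genes, which are not independent replicates. In 100 simulations without effects the mean r was -0.00268 (SD 0.0196). Genes were drawn independently there, so this SD leaves out genes that vary together and unrelated differences between lines. It does not measure how far r could lie from 0 for such reasons. Genes that rose on knockdown fell as a set between the rescues and those that fell rose, by fry of limma, a rotation test whose p-values of 0.0193 and 0.0170 are not permutation p-values; camera gave 0.306 and 0.362. FASN and CHAC1 fell on knockdown and rose in the mutant rescue, as did INSIG1, whereas CCL20 (-0.61, SE 0.06) and ACPP (-1.20, SE 0.06) rose on knockdown and fell between the rescues.

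Against the control, the wild-type rescue kept PGK1 at a log2 fold change of -2.06 (SE 0.02), CCL20 at 2.71 (SE 0.08), SI at 2.89 (SE 0.18) and UGT2B15 at 2.22 (SE 0.07). IGFBP3, which binds insulin-like growth factors, was higher by 2.23 (SE 0.07) and KLK3 lower (-0.31, SE 0.02). By edgeR 3636 genes were higher and 3895 lower (DESeq2, 4995 genes), and 5334 of the 7337 knockdown calls, 72.7%, were called in the same direction against 1810 expected by independence. These comparisons share the control libraries; with 1 control library for each comparison, chosen after seeing the data, 4000 against 1210 expected and 3958 against 1198 were called in the same direction. Knockdown calls reversed by wild-type METTL3 numbered 1618 against 877.4 expected by independence, and those reversed by the mutant 2753 against 1898, but these comparisons share the knockdown libraries, which favours opposite directions. With 1 knockdown library for each comparison, the wild-type reversed 1074 against 545 and 937 against 495, and the mutant 2027 against 1320 and 2045 against 1341. These splits still take both libraries from 1 line. A trait of the knockdown line would thus favour opposite directions, and a trait of the control line the same direction. The covariance of knockdown and rescue changes was -0.0304 for the wild-type and -0.0489 for the mutant, of which the shared libraries give -0.0172 and -0.0173 in simulations. Fold changes of the knockdown and of the wild-type rescue, each against the control, had r = 0.842 and a covariance of 0.159, of which the shared control gives 0.0181 in simulations. Of 40 androgen-induced genes 30 were lower than control and 4 higher in the wild-type rescue (30 and 5 adjusted over the list alone; camera adjusted p = 4.59e-15, and 0.0318 with an estimated correlation), including KLK2 at -0.97 (SE 0.02).

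**Figure D4:**
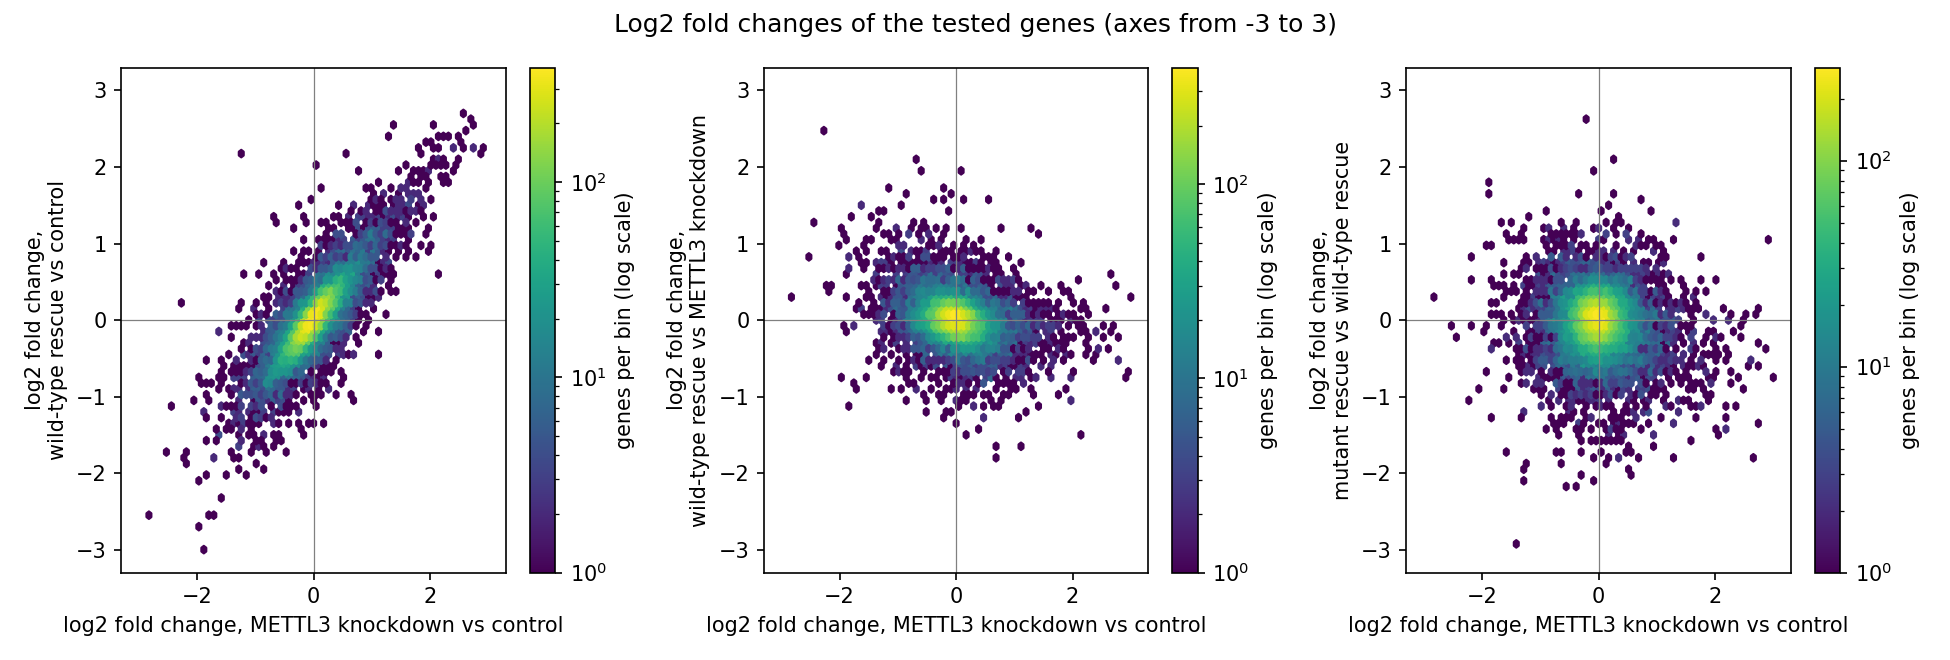
Log2 fold changes of the tested genes (colour, genes per bin on a log scale) on knockdown (x) against wild-type rescue over control, wild-type rescue over knockdown and mutant rescue over wild-type rescue (y). The first panel follows a rising line (r = 0.842, covariance 0.159). Of this covariance the shared control libraries give 0.0181 in simulations without effects. The mean r of 0.515 in those simulations is not a part of 0.842, because only noise varied there. The last, whose comparisons share no library, is nearly round (r = -0.127, simulated mean -0.00268).

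In the mutant rescue against the control, METTL3 was higher by 2.29 on the log2 scale (SE 0.03), CCL20 by 2.10 (SE 0.09), HMOX1 by 2.10 (SE 0.06) and CP, ceruloplasmin, by 1.97 (SE 0.07). OR51E1 was lower (-2.42, SE 0.16), as were UFSP1 (-2.25, SE 0.19), PGK1 (-2.16, SE 0.02) and PCAT1 (-1.84, SE 0.08). By edgeR 4451 genes were higher and 4542 lower. MYC targets were lower in 36 of 36, in both forms of the count, with MYC itself at -1.25 (SE 0.02; camera adjusted p = 7.71e-27; adjusted p = 0.0568 with an estimated correlation, or 0.0474 with the length trend also removed).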

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

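The comparison of the rescues and its correlation with the knockdown changes were planned; the other tests in this part, and the reading of that correlation as a test of an explanation, were chosen after the results were seen.

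Against the knockdown, 2768 genes were called in the same direction in both rescues. Both comparisons share the knockdown libraries, which favours the same direction. The change on adding wild-type METTL3 to the knockdown and the change on adding the mutant differed in 6307 genes by the edgeR test of the difference. In 167 of these the rescues went in opposite directions. ZBTB16, a zinc finger transcription factor, had log2 fold changes of -0.30 (SE 0.06) with the wild-type and 0.32 (SE 0.05) with the mutant. The cystine transporter SLC7A11 had -0.24 (SE 0.04) and 0.23 (SE 0.04), and the WNT inhibitor APCDD1 0.23 (SE 0.07) and -0.81 (SE 0.08). Loss of catalytic activity as the whole cause of both the knockdown changes and the differences between the rescues was read as needing a positive correlation between them. This assumes that genes respond in the same direction to METTL3 below the control level and above it, where both rescues lay. The r was -0.127, or -0.0435 without a filter on low counts and -0.0755 from a mean of 10 CPM (Spearman rho -0.0612). Its size depends on these choices, and it was above 0 under none of the alternatives run. Without that assumption r does not decide the question. A part played by activity in single genes stays open, as do differences between separately selected lines, because each rescue is 1 line.

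Of the genes called on knockdown, 72.7% were called in the same direction in the wild-type rescue against the control, PGK1, CCL20 and UGT2B15 among them. Both comparisons use the control libraries; with 1 control library for each, the shares were 66.2% and 65.6%. Too little METTL3 transcript in the rescue is argued against by its log2 fold change of 2.21 over the control, though protein was not measured. Effects of the hairpin on other transcripts, or differences between separately selected cultures, may explain the remaining changes, and these cannot be told apart because the control line is the only one without the METTL3 hairpin.

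On adding wild-type METTL3, log2 fold change fell with gene length by -0.0709 per doubling of length (-0.0747 to -0.0662 with a library left out). Catalytic activity of the introduced enzyme is argued against by the slope between the rescues of -0.00160 (-0.00629 to 0.00218 with a library left out), since the mutant gave the same trend against the knockdown (-0.0725). Methylation of transcripts with long exons would make the longest exon count beyond spliced length, and its partial rank correlation was 0.0440. A length bias of the libraries may also give such a trend; the largest slope within a pair of libraries was 0.00842, but a bias shared by a group cannot be told apart from an effect of the group.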

How the results depend on the processing

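The alternative without the length trend was chosen after seeing the data; the others were planned. The 887 values of named genes gave 12418 values under the alternatives, of which 12100 kept their direction and side of the threshold, 317 kept their direction but lost the call, 0 gained one and 1 reversed: FN1 in the mutant rescue against the knockdown, at -0.11 and with the length trend removed at 0.00961. Calls with the DESeq2 Wald test numbered 4767 (knockdown), 1705 (wild-type rescue against knockdown), 3749 (mutant against wild-type rescue) and 4995 (wild-type rescue against control); the cause was not tested. With a minimum absolute log2 fold change of 1, calls numbered 514, 35, 380, 185, 491 and 837 for knockdown, wild-type and mutant rescue against knockdown, mutant against wild-type rescue, and wild-type and mutant rescue against control, fewer by construction. In that order an estimated correlation called 6, 0, 0, 6, 7 and 0 lists; fry, which does not compare a list with other genes, called 27 (knockdown), 19 and 32 (rescues against knockdown), 29 and 30 (rescues against control). The correlation of knockdown changes with those between the rescues was -0.127, or -0.0435 without a filter on low counts. It was -0.0755 from a mean of 10 CPM and -0.120 to -0.0881 with a library left out. That of knockdown and mutant rescue changes was -0.276, or -0.462 without the filter and -0.179 from a mean of 10 CPM. The cause of these differences was not tested. For knockdown and mutant rescue changes, simulations without effects gave a mean r of -0.487, where only noise varied. This mean is therefore not a part of -0.276. The shared knockdown libraries gave -0.0173 of the covariance of -0.0489. With a library left out, calls numbered 6020 to 7435 on knockdown, 2473 to 3680 and 6631 to 7978 for the rescues against knockdown and 4959 to 6289 between the rescues. Replicate numbers do not pair the samples (correlations of deviations -0.0424 to 0.0250), and as a block they gave 7369, 3717, 7930, 6340, 7563 and 9004 calls. In simulated data of this design 50% of genes with a log2 fold change of 0.25 were called with the right sign and 98% at 1, which limits what a missing call shows. Far fewer genes were changed there than were called here, which makes the adjusted threshold stricter. The simulated shares may therefore be too low for the real data.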

Other observations

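The tests on wild-type rescue replicate 1 in this part were chosen after the result was seen; the lists were planned.

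Some groups showed no call on knockdown. Of 12 basal epithelial markers 2 rose and 2 fell on knockdown, the same counts adjusted over the list alone (camera adjusted p = 0.773), and of 11 neuroendocrine genes 2 rose and 2 fell (2 and 1 adjusted over the list alone; camera adjusted p = 0.928). Among 27 genes of the methylation machinery 6 rose and 10 fell on knockdown, in both forms of the count, with RBMX at -0.35 and METTL14 at 0.24 on the log2 scale (camera adjusted p = 0.377). That list, which holds METTL3 itself, was called upward in the mutant rescue against the knockdown, with 13 rises and 4 falls (15 and 5 adjusted over the list alone; camera adjusted p = 0.0165; adjusted p = 0.108 with an estimated correlation). Against the wild-type rescue it had 13 rises and 3 falls (14 and 3 adjusted over the list alone; camera adjusted p = 0.00484; adjusted p = 0.0708 with an estimated correlation). By contrast, 7 nuclear-retained RNAs were called downward on knockdown, with 4 falls and 1 rise (camera adjusted p = 0.0452, or 0.191 with an estimated correlation). That call ended without a filter on low counts (camera adjusted p = 0.0995) and with some single libraries left out. In the mutant against the wild-type rescue 5 of these RNAs rose with no fall (camera adjusted p = 1.55e-04, or 0.0505 with an estimated correlation). With the length trend removed, an alternative chosen after seeing the data, the list was called upward against the knockdown in both rescues. The wild-type rescue had 4 rises and no fall (camera adjusted p = 5.75e-10, or 0.0890 with an estimated correlation). The mutant rescue had 5 rises and no fall (camera adjusted p = 1.72e-07, or 0.0431 with an estimated correlation). The spliceosomal RNA gene RNU6-2, singled out after its values were seen, had 843 and 4387 counts in the control libraries.

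In wild-type rescue replicate 1, 14 genes with at least 20 counts, picked out after their values were seen, stood over 3 times above every other library. Sampling noise alone around the group means gave at most 1 such gene in any library in 100 simulations, which argues against it as the source. BASP1 had 163 counts there and 39 in replicate 2, S100A6 77 and 10, AKR1B1 72 and 10, SERPINH1 40 and 7, and GSTP1 38 and 5. RNA of other cells in that library may be a source, but this stays open: of 54 basal, mesenchymal and fibroblast markers, the 28 that were low in the other lines summed to 198 counts in replicate 1 against 106 in replicate 2, a ratio per total count of 2.18. The 95% interval of 1.72 to 2.79 covers counting error only. The same ratio was 0.734 in the control, 1.09 in the knockdown and 1.43 in the mutant rescue, and the spread of these 3 pairs allows a ratio of up to 2.43, so the marker test does not decide. Over whole lists, basal markers stood at 73.1 and 60.1 CPM in replicates 1 and 2, fibroblast markers at 127.6 and 117.6, and mesenchymal markers at 742 and 710.3. Without wild-type rescue replicate 2, basal (camera adjusted p = 0.0124) and mesenchymal markers (0.00625) were called upward against the knockdown, where the full data gave 0.480 for each. No other source was tested.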
